A study of Homo sapiens with 3 samples.

How the data were processed

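Total RNA was isolated with TRIzol from the human ES lines H9, BG03 and ES01, labelled with Cy3 using an Agilent kit and hybridised to Agilent whole-genome arrays, 1 array per line, per the labels. The lines form a single group with replicates 1 (H9), 2 (BG03) and 3 (ES01). The arrays sat on the same slide, at positions 3, 4 and 2, and were scanned together, so line and position cannot be told apart and there was no batch to compare.

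The authors deposited the scanner output of Agilent Feature Extraction 9.1.3.1, 1 text table per array with 45015 spots. Per the file headers, the processed signal is an intensity on a linear scale from which Feature Extraction removed local background and spatial trends within the array, with a substitute value for dim spots and no normalization between arrays. The mean and local background signals are unprocessed intensity. The well-above-background, saturation and outlier columns are, per the file headers, flags (other than a measurement). The deposited value table of the series holds an intensity that matched the processed signal rounded to 3 digits (largest difference under 0.5%); its medians were 167 (H9), 149 (BG03) and 166 (ES01), and it is neither log-transformed nor centred.

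Control spots (1639 per array) and outlier-flagged spots (28 in H9, 18 in BG03 and 18 in ES01) were removed. The level of a probe was log2 of the processed signal minus the array's 75th percentile, averaged over the spots of the probe. The 41000 probes were named through a table of RefSeq genes on assembly GRCh38.p14, used for names and chromosomes only: 23434 matched by accession, 2317 by symbol and 1043 by synonym, and 14206 matched no gene and were kept apart. XIST and genes of the Y chromosome were left out of everything (114 probes, with those lacking an unflagged spot), and the sex chromosomes were left out of the grouping by chromosome. A gene was represented by its probe with the highest mean signal (17449 genes, 6859 of them with several probes), and differences between lines were taken within a probe. HLA genes were not named.

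A gene was detected when Agilent's flag put it well above background on all 3 arrays. Detected shares were compared with Fisher's exact test, two-sided, and adjusted over the 22 lists by Benjamini-Hochberg. With 1 array per line there are no residual degrees of freedom between lines, so no gene was tested between lines. A gene was called apart in a line when it differed there by at least 1 on the log2 scale (2-fold) from each other line in the same direction and its brighter side was well above background. Where the dimmer side was not well above background the fold is a bound, computed against the lowest signal among probes well above background on that array or the dim probe's own signal, whichever was higher. A list was described in a line by the median over its genes of that line minus the mean of the other lines, and its spread by the median SD between lines, each placed among 10000 random lists of the same size matched on mean level in 20 bins. Lists with at least 5 genes well above background on at least 1 array were used. The random-list permutation p is two-sided and was adjusted over the pairs of list and line; the smallest that 10000 lists can give is 0.0002. Genes within a list are not independent, so these p measure distance from random lists, not replication. Autosomes were treated as lists in the same way.

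The design, the lists and the rule for named genes were fixed before the data were examined. The 14 pathway lists were core pluripotency, mouse ES-biased, EpiSC-biased, Activin and Nodal pathway, LIF and BMP pathways, FGF pathway, DNA methylation and Polycomb, cell cycle, imprinted, hypoxia and glycolysis, stress response, cholesterol synthesis, a chromosome 20 segment often gained in culture, and housekeeping. The 8 cell type lists were neuroectoderm, mesoderm, endoderm, trophoblast, germ cell, fibroblast, blood and endothelium, and epithelium and surface ectoderm. They were drawn from general knowledge, and some genes stand in several. The text could name list members, the 8 higher and 8 lower genes per line with the largest smaller difference to the other lines, the 4 with the largest bound per line, and the 10 with the smallest and the 10 with the largest SD.

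Alternatives were detection by the 99th percentile of the negative controls, by a limma test (limma 3.58.1 in R 4.3.3) or on at least 1 or 2 arrays; normexp background correction with an offset of 50; quantile normalization; median centring; all probes of a gene averaged; the deposited value table; other filters on dim probes; thresholds of 1.5-fold and 4-fold; and leaving out each line. Detection at 10 and 100 times the negative controls, and 2 further gene lists (liver and yolk sac secreted proteins, and further HIF targets) with the protocadherin genes, were added after the data had been seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

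The steps were tested on simulated data with 17449 genes. Genes set apart in a line were recovered in 34% of cases at 2-fold, 98% at 3-fold and 100% at 4-fold and 8-fold, and 0% of unchanged genes were called. Every gene of that simulation had the same noise, set to the median SD between lines (0.19). Measured SDs reached 0.58 at the 95th percentile, so the 0% is no rate of false calls for the measured arrays. Unchanged lists fell outside the random range in 2.33% of cases for a line and 3% for the spread, and lists of 20 genes raised by 0.3 in 100%. These lists held randomly drawn genes with independent noise. The 2.33% and 3% are thus no rates of false calls for the measured lists, whose genes may vary together. The limma detection step, on 4000 simulated genes, called 100% of genes 4-fold above the negative controls and 0% of those at their level.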

Results

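Total RNA from 3 human embryonic stem (ES) cell lines, H9, BG03 and ES01, was measured on Agilent whole-genome oligonucleotide arrays in 1 colour. Each line was grown undifferentiated on irradiated mouse embryonic fibroblast feeders in medium with FGF2 and contributed 1 array. Whether feeder RNA added to any signal was not tested. The lines are the 3 replicates of a single group, so every SD given here is the spread between lines together with culture and array noise. The study set human ES cells beside mouse ES cells and mouse epiblast stem cells (EpiSCs), pluripotent cells taken from the epiblast after implantation; the mouse arrays were not analysed here. Of the 43376 gene spots on each array, 83.3% were well above background in H9, 82.0% in BG03 and 85.6% in ES01. The median signal was 182 intensity units in H9, 160 in BG03 and 180 in ES01, against 2.89 to 3.58 for the negative controls, and no spot was saturated. The number of arrays limits the precision of every value.

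The first question was which genes the human ES lines express. Of 17449 genes with a usable probe, 15396 (88.2%) were well above background on all 3 arrays, 828 on 1 or 2 arrays and 1225 on none. All 25 genes of the core pluripotency list were detected in every line. POU5F1, the transcription factor that marks the pluripotent state, had a level of 8.18 ± 0.13 (log2 signal minus the array's 75th percentile; mean ± SD, n = 3). The levels of its partners were 4.92 ± 0.23 for SOX2, 4.54 ± 0.19 for NANOG and 5.04 ± 0.16 for SALL4. DNMT3B, a de novo DNA methyltransferase, was at 7.10 ± 0.14 and TERF1, a telomere-binding protein, at 5.42 ± 0.12. The RNA-binding proteins L1TD1 and LIN28A were at 6.60 ± 0.16 and 2.11 ± 0.15. CRIPTO (formerly TDGF1), the Nodal co-receptor, was at 5.51 ± 0.17. The SD between lines was under 0.5 for 24 of the 25 genes. The exception was NODAL, with levels of -0.09 in H9, 0.22 in BG03 and 0.96 in ES01.

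**Figure D1:**
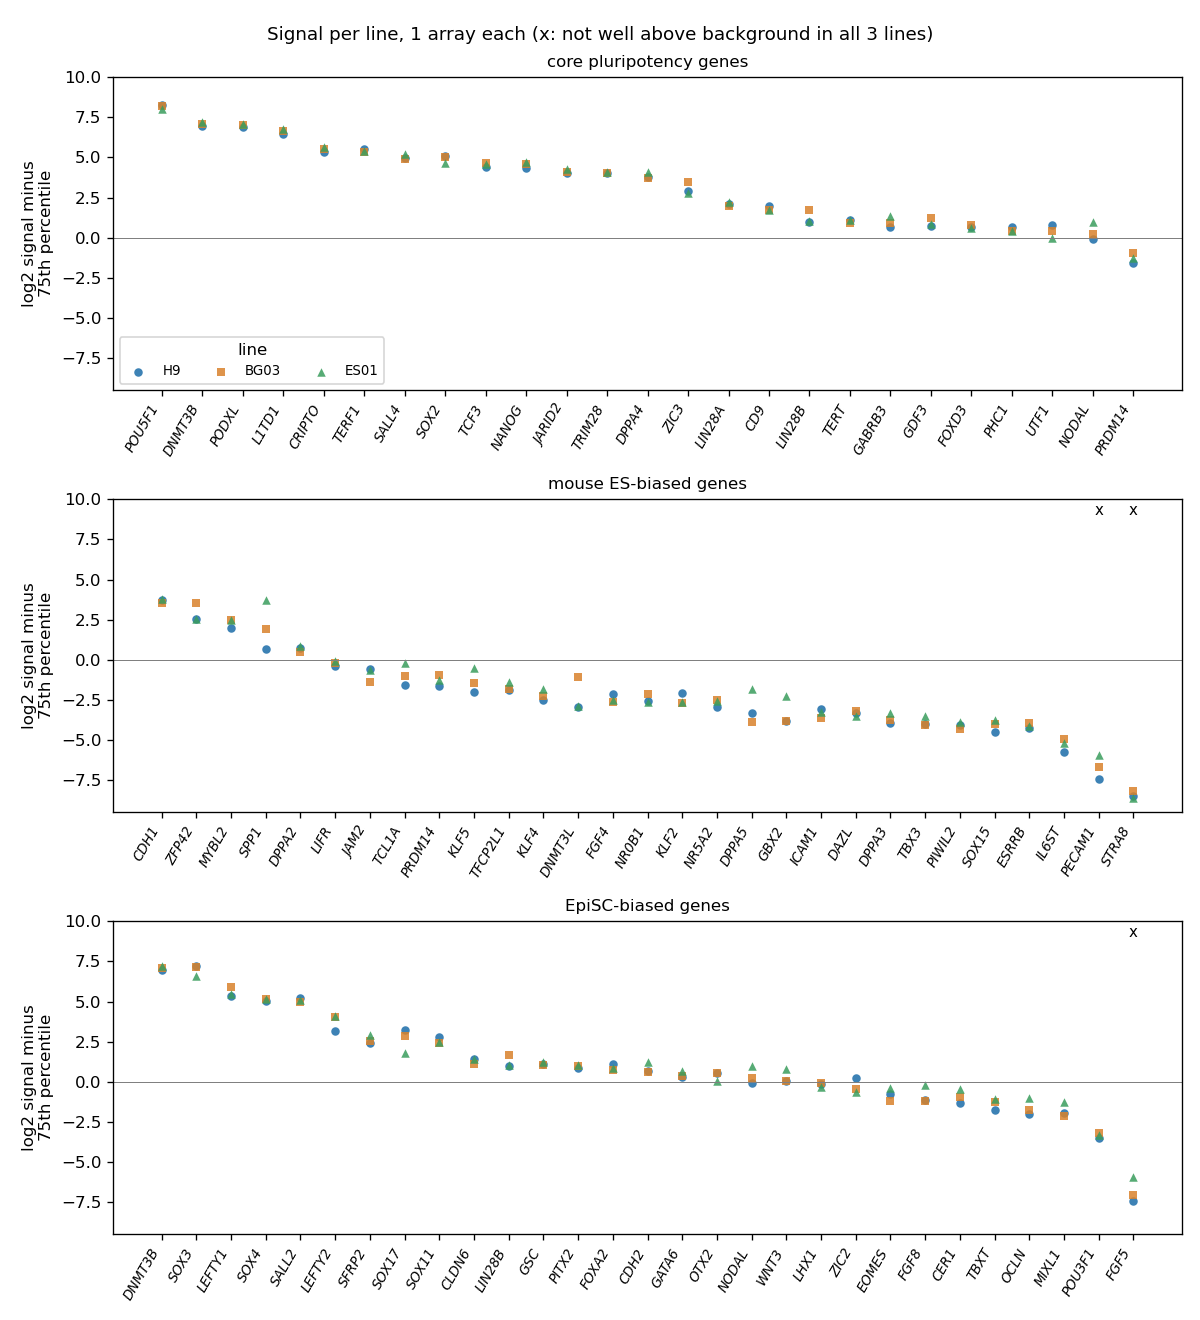
Signal of each core pluripotency, mouse ES-biased and EpiSC-biased gene (x axis) in each line, as log2 signal minus the array's 75th percentile (y axis); each point is 1 array, a cross marks a gene not well above background in all 3 lines, and levels of different genes come from different probes and are not to be ranked. The points of the 3 lines lie close together for POU5F1 (8.04 to 8.29) and far apart for SPP1 (0.66 to 3.73).

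The second question was how the human lines stand with respect to genes that differ between mouse ES cells and EpiSCs. In all 3 lines 27 of 29 mouse ES-biased genes (93.1%) and 28 of 29 EpiSC-biased genes (96.6%) were detected (p = 1, two-sided Fisher's exact test). The flag was met by 88.2% of all genes, so both lists lay near the ceiling and this test could hardly tell them apart. Of the mouse ES-biased genes, STRA8, a meiotic entry gene, was not well above background in any line and PECAM1, a cell adhesion molecule, was so only in ES01. The transcription factors ESRRB (-4.09 ± 0.15), TBX3 (-3.85 ± 0.31), KLF4 (-2.20 ± 0.34) and NR0B1 (-2.44 ± 0.29) and the germline-associated gene DPPA3 (-3.66 ± 0.29) were detected in every line. ZFP42, a zinc finger gene used as a marker of mouse ES cells, was at 2.86 ± 0.57. Of the EpiSC-biased genes, the Nodal antagonists LEFTY1 (5.57 ± 0.28) and LEFTY2 (3.78 ± 0.53), the neural and epiblast factors SOX11 (2.55 ± 0.20) and OTX2 (0.39 ± 0.29) and the endoderm factors SOX17 (2.60 ± 0.74), FOXA2 (0.90 ± 0.19) and GATA6 (0.46 ± 0.19) were detected in every line, as were the primitive streak genes EOMES (-0.76 ± 0.40) and TBXT (-1.36 ± 0.35). FGF5, a ligand of the early epiblast, was well above background only in ES01.

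The lists parted at a signal threshold chosen after the data had been seen. A signal of at least 100 times the 99th percentile of the negative controls on all 3 arrays was reached by 6 of 29 mouse ES-biased genes (20.7%) and 21 of 29 EpiSC-biased genes (72.4%; p = 0.00017, two-sided Fisher's exact test), and by 8358 (47.9%) of all genes. The 6 were ZFP42, DPPA2, SPP1, LIFR, CDH1 and MYBL2. The 8 EpiSC-biased genes under the threshold were FGF5, TBXT, EOMES, CER1, POU3F1, MIXL1, FGF8 and OCLN. At 10 times the negative controls the counts were 26 and 28 (p = 0.611, two-sided Fisher's exact test). Signal depends on the probe as well as on the transcript, so such shares do not rank transcripts.

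Markers of 2 lineages were detected less often than other genes. Of the neuroectoderm list 11 of 22 genes were detected in all lines, against 88% of other genes (adjusted p = 0.000261, two-sided Fisher's exact test, 22 lists). Of the trophoblast list 10 of 19 genes (52.6%) were (adjusted p = 0.00143, two-sided Fisher's exact test). The neural genes NEUROG2, NEUROD1, ZIC1, SIX6 and NCAM1 and the trophoblast genes TFAP2A, TP63, CGA and LGALS13 were not well above background in any line. Among neuroectoderm genes that were detected in every line, SOX1 was at 3.52 ± 0.38, NES, an intermediate filament of progenitors, at 2.67 ± 0.44, and TUBB3, a tubulin of neurons, at 5.07 ± 0.40. These 2 calls ended (0 lists) when detection was a signal above the 99th percentile of the negative controls, a limma test against the negative controls, or a flag on at least 1 array.

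The other lists did not pass the test. Every measured gene was detected in all lines for the lists Activin and Nodal pathway (25), cell cycle (26), stress response (25), hypoxia and glycolysis (20), cholesterol synthesis (20), housekeeping (20) and a chromosome 20 segment often gained in culture (18). Detection was 24 of 25 for the LIF and BMP pathways, 20 of 23 for the FGF pathway, 16 of 18 for DNA methylation and Polycomb and 25 of 28 for imprinted genes. It was 17 of 20 for endoderm, 15 of 21 for mesoderm, 13 of 19 for germ cells, 21 of 25 for fibroblasts, 16 of 23 for blood and endothelium and 17 of 20 for epithelium and surface ectoderm. The smallest adjusted p among these was 0.101, for both germ cells and blood and endothelium (two-sided Fisher's exact test).

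The third question was how far the lines differ from each other. Over the 15396 detected genes Pearson's r was 0.988 between H9 and BG03, 0.985 between H9 and ES01 and 0.989 between BG03 and ES01; these correlations run across genes, which are not independent replicates. A difference of over 2-fold was seen for 416 genes (2.70%) between H9 and BG03, 680 (4.42%) between H9 and ES01 and 444 (2.88%) between BG03 and ES01. The median SD between lines was 0.19 and 145 genes had an SD over 1. Repeated spots of a probe on the same array had a median SD of 0.07 to 0.08, which covers spot noise only. Among the genes with the smallest SD were the Mediator subunit MED4 (3.53 ± 0.0029, n = 3) and the zinc finger gene ZNF3 (0.86 ± 0.0024, n = 3). Among those with the largest were ARMCX5 (-0.93 ± 3.13), BEX5 (-2.37 ± 2.74), the protocadherin PCDHB5 (-1.51 ± 2.74) and IAH1 (-2.56 ± 2.58).

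Pluripotency, housekeeping and proliferation genes varied between lines no more than random lists, whereas several signalling and lineage lists varied more. The median SD between lines was 0.16 for core pluripotency, 0.15 for housekeeping, 0.17 for cell cycle, 0.14 for cholesterol synthesis and 0.15 for DNA methylation and Polycomb genes, inside the central 95% of 10000 random lists matched on level. It was above that range for 11 of 22 lists. The EpiSC-biased list had a median SD of 0.33 against 0.17 for random lists (adjusted random-list permutation p = 0.0044) and the endoderm list 0.44 against 0.23 (adjusted permutation p = 0.0044). The others were mesoderm (0.41 against 0.23), fibroblast (0.32 against 0.18), mouse ES-biased (0.31 against 0.22), FGF pathway (0.30 against 0.19), hypoxia and glycolysis (0.30 against 0.17), Activin and Nodal pathway (0.28 against 0.18) and imprinted genes (0.27 against 0.18), with adjusted permutation p from 0.0088 to 0.0381. Neuroectoderm (0.40 against 0.25) and stress response (0.22 against 0.15) lay outside the range but missed the adjusted threshold (adjusted permutation p = 0.0524 and 0.0616). The LIF and BMP pathways (0.24), the chromosome 20 segment (0.20), trophoblast (0.37), germ cell (0.31), blood and endothelium (0.30) and epithelium (0.27) lay inside. With all probes of a gene averaged, 7 lists lay above the range, and without H9, without BG03 or without ES01 the number was 5, 8 or 7.

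Among imprinted genes the largest SD belonged to NNAT, at -3.97 in H9, -3.30 in BG03 and -1.88 in ES01, 2.68-fold higher in ES01 than in BG03. ATP10A was at -1.20 in H9, 2.63-fold above BG03. H19, a maternally expressed non-coding RNA, was at -4.02 in ES01 and -2.52 in H9, 2.85-fold higher in H9. MEG3 (0.46 ± 0.11) and GNAS (5.65 ± 0.09) varied little, and SNRPN (3.58 ± 0.25) had an SD near the list's median of 0.27.

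Counted line by line, 659 genes (3.78%) differed at least 2-fold in a line from each of the other lines, in the same direction; 36 of them did so for a pair of lines, which gives 695 differences. With 1 array per line there was no test between lines. In H9, 127 genes were higher and 127 lower. SLC16A3, a lactate exporter, was at 2.70 in H9 and at -0.28 and -0.42 in BG03 and ES01, 7.89-fold above the nearer line. TTR, a serum protein made in yolk sac and liver, was at 0.10 against -4.70 and -2.77, 7.29-fold above ES01. DDIT4, a stress-responsive inhibitor of mTORC1, was 4.54-fold higher, CD86, an immune co-stimulatory molecule, 5.12-fold and NPTX1, a neuronal pentraxin, 4.14-fold. The lower genes had wider gaps. BEX5 was 20.9-fold lower, PSMD5, a proteasome assembly factor, 20.3-fold, PUS7L 16.5-fold, HENMT1, which methylates small RNAs of the germline, 12.5-fold and REC8, the meiotic cohesin, 11.1-fold. TSPYL5, TUSC1, DYNLT3 and DCAF12L1 were not well above background in H9 and were at least 43.8-fold, 40.2-fold, 32.4-fold and 16.6-fold lower there.

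In BG03, 64 genes were higher and 128 lower. ARMCX5 was at -4.55 in BG03 and at 0.83 and 0.92 in H9 and ES01, 41.6-fold below the nearer line. Of the protocadherin beta genes, which encode neural cell adhesion molecules, PCDHB5 was 16.9-fold lower, PCDHB12 5.79-fold and PCDHB15 5.42-fold. The non-coding RNA LINC00479 was 12.7-fold lower and WDR90 8.95-fold, the latter with all 3 of its other probes in the same direction. MAB21L2, a developmental gene of eye and midbrain, was at 1.49 against -2.51 and -1.24, 6.62-fold above ES01. MCAT, an enzyme of mitochondrial fatty acid synthesis, was 3.91-fold higher, the mesodermal factor TBX15 3.74-fold, the cytokine subunit IL27 3.46-fold and DNMT3L, a cofactor of the de novo DNA methyltransferases, 3.44-fold. FGF7 was not well above background in H9 or ES01 and was at least 20.5-fold higher in BG03. ZNF229, PTPRN2 and ZNF528 were not well above background in BG03 and were at least 14.5-fold, 4.95-fold and 4.89-fold lower there.

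In ES01, 179 genes were higher and 70 lower. IAH1 was at 0.42 in ES01 and at -4.12 and -3.98 in H9 and BG03, 21.2-fold above the nearer line. COX7A1, a subunit of cytochrome c oxidase, was 6.62-fold higher, the lysosomal protease CTSF 6.55-fold, the fatty acid transporter CD36 5.83-fold, the glutamate transporter SLC1A6 5.81-fold and CAT, catalase, 4.37-fold. CR1L, CCDC125, ZNF560 and RBM46 were at least 14.2-fold, 11.9-fold, 10.2-fold and 8.19-fold higher; of these, CCDC125 and RBM46 were well above background in BG03 too. ZNF558 was 6.13-fold lower, SORBS2 4.09-fold, the mesodermal factor FOXC1 3.65-fold, IDO1, which degrades tryptophan, 3.59-fold, the interferon-induced BST2 3.33-fold and the Wnt receptor FZD8 3.33-fold. The mouse ES-biased genes SPP1 (osteopontin), GBX2 and DPPA5 were also apart in ES01, 3.57-fold, 2.93-fold and 2.84-fold above the nearer line.

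Different probes of a gene gave a check on these calls. Among 190 other probes of those genes 161 (84.7%; 95% exact Clopper-Pearson interval 78.8 to 89.5%) differed in the same direction, and 60 did so by at least 2-fold. The share was 28 of 44 (63.6%, interval 47.8 to 77.6%) for genes higher in H9 and 133 of 146 (91.1%, interval 85.3 to 95.2%) for the rest. Within the rest it was 26 of 33 for genes lower in ES01. After normexp background correction, which compresses dim signals, 244 of the 695 differences remained.

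Whole lists were set against random lists, for each line against the mean of the other lines. Of 66 pairs of list and line 25 lay outside the central 95% of random lists, and 18 had an adjusted permutation p under 0.05. For lists of unrelated genes 3.3 would be expected outside. Genes of a list may vary together, so 3.3 is no rate of false calls for these lists. The lists also share genes and the shifts of the 3 lines are not independent, so the 25 pairs are not separate observations. With a line left out, so that the 2 remaining lines are compared directly, 5 to 9 of 22 lists lay outside.

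In H9, pluripotency and signalling lists were lower and endoderm markers higher. The core pluripotency list had a median difference of -0.19 with 17 of 25 genes lower (adjusted permutation p = 0.00792), the mouse ES-biased list -0.40 with 21 of 28 lower (0.0066) and the EpiSC-biased list -0.21 with 19 of 29 lower (0.00792). The Activin and Nodal list was at -0.26 with 21 of 25 lower (adjusted permutation p = 0.0099), the FGF list at -0.31 with 15 of 23 lower (0.00825) and epithelium and surface ectoderm at -0.33 with 16 of 18 lower (0.00825). Single members went the other way, such as POU5F1 at 8.29 in H9 against 8.21 in BG03 and 8.04 in ES01 and FGFR1 at 3.27 against 2.95 and 2.82. LEFTY2 was at 3.16 in H9 against 4.05 and 4.12 in BG03 and ES01, and DUSP6, a feedback phosphatase of FGF signalling, at 0.44 against 0.94 and 1.61. The endoderm list was at 0.32 with 12 of 19 genes higher (adjusted permutation p = 0.00825). Besides TTR, the serum protein genes AFP, ALB, APOA1, APOA2 and APOB all had their highest level in H9, with APOA1 at -0.62 against -0.94 and -1.86 and AFP at -4.16 against -5.94 in ES01; AFP and ALB were not well above background in BG03. The transcription factors of the list went both ways. GATA4, GATA6 and SOX7 had their lowest level in H9, with GATA4 at -2.83 against -2.50 and -1.97. SOX17 (3.20 against 2.83 and 1.78) and FOXA2 (1.11 against 0.74 and 0.84) had their highest level there. Of the 20 measured endoderm genes 11 were highest and 6 lowest in H9. Hypoxia and glycolysis genes were at 0.16 with 15 of 20 higher, outside the random range but short of the adjusted threshold (adjusted permutation p = 0.078). BNIP3, a mitophagy receptor induced by hypoxia, was 2.06-fold above BG03 and 2.68-fold above ES01, and LDHA, lactate dehydrogenase, 1.59-fold and 1.72-fold. Other hypoxia targets had their lowest level in H9: ADM was at 2.96 against 3.63 and 3.91 and NDRG1 at -0.85 against -0.60 and -0.32. The FGF, epithelium and endoderm lists stayed outside the random range under all 9 alternatives. Their sizes moved, with medians from -0.50 to -0.20 for FGF, -0.40 to -0.24 for epithelium and 0.15 to 0.50 for endoderm genes. Set against BG03 alone the mouse ES-biased (-0.23), Activin and Nodal (-0.13) and EpiSC-biased lists (-0.05) lay inside it, as did core pluripotency (-0.08) and EpiSC-biased genes (-0.13) with all probes averaged and hypoxia genes (0.13) against ES01 alone.

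In BG03, hypoxia and glycolysis genes were lower than the mean of the other lines (-0.18, 17 of 20 lower, adjusted permutation p = 0.0088); against ES01 alone the median was -0.12, inside the random range. Fibroblast genes were at -0.14 with 13 of 22 lower (adjusted permutation p = 0.0405), a call lost under 4 of 9 alternatives. Of its members DCN, decorin, was at -0.74 in BG03 against 1.27 in H9 and 0.48 in ES01, and COL3A1, a fibrillar collagen, at -2.09 against 0.09 and -1.47. LUM, lumican, went the other way, at -3.85 against -6.02 (not well above background) and -5.91, as did the collagen COL5A2, at 1.49 against 1.04 and 1.01. The cultures held mouse fibroblast feeders, and whether feeder RNA added to the fibroblast signals was not tested. Mouse ES-biased genes were at -0.13 with 16 of 28 lower (adjusted permutation p = 0.0499), but against H9 alone the direction turned to 0.23. Mesoderm genes were higher (0.24, 11 of 19, adjusted permutation p = 0.0315), inside the random range against H9 alone (0.21). Epithelium and surface ectoderm genes were at 0.24 with 13 of 18 higher (adjusted permutation p = 0.0096); against ES01 alone the median was -0.008, so this call rested on H9. EpiSC-biased genes (-0.11, 17 of 29 lower) and stress response genes (-0.11, 17 of 25 lower) lay outside the random range and missed the adjusted threshold (adjusted permutation p = 0.0577 and 0.078); against H9 alone the EpiSC-biased median turned to 0.05.

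In ES01 the FGF list was at 0.40 with 16 of 23 genes higher (adjusted permutation p = 0.0066), Activin and Nodal at 0.29 with 19 of 25 higher (0.00792), mouse ES-biased at 0.25 with 20 of 28 higher (0.0096) and EpiSC-biased at 0.16 with 20 of 29 higher (0.0405). The FGF, mouse ES-biased and EpiSC-biased lists stayed outside the random range under all 9 alternatives, whereas Activin and Nodal lay inside it against BG03 alone (0.07) and with all probes averaged (0.12). Sizes moved, with medians from 0.21 to 0.50 for FGF, 0.20 to 0.39 for mouse ES-biased and 0.13 to 0.19 for EpiSC-biased genes. DNA methylation and Polycomb genes were at 0.21 with 11 of 18 higher (adjusted permutation p = 0.045), a call lost under 3 of 9 alternatives, with a median of -0.0011 when all probes of a gene were averaged. NODAL was 2.07-fold above H9 and 1.67-fold above BG03, and DUSP6 2.25-fold and 1.60-fold. Mesoderm genes were at -0.18 with 12 of 19 lower (adjusted permutation p = 0.0445); FOXC1 and the myosin light chain MYL4 were 3.65-fold and 3.19-fold below H9, while the cardiac actin ACTC1 was at 4.52 in ES01 against 3.66 in H9 and 3.46 in BG03. Against H9 alone the mesoderm median was -0.045, inside the random range. Germ cell (0.27), blood and endothelium (0.27), epithelium (0.18) and endoderm genes (-0.12) lay outside the random range with adjusted permutation p from 0.078 to 0.119; against BG03 alone the endoderm median turned to 0.18 and the epithelium median was 0.008. Fibroblast genes lay inside the range in H9 (-0.0048, 11 of 22 higher) and in ES01 (0.08, 12 of 22 higher). The LIF and BMP, cell cycle, imprinted, cholesterol, housekeeping, chromosome 20, neuroectoderm and trophoblast lists lay inside the range in every line.

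**Figure D2:**
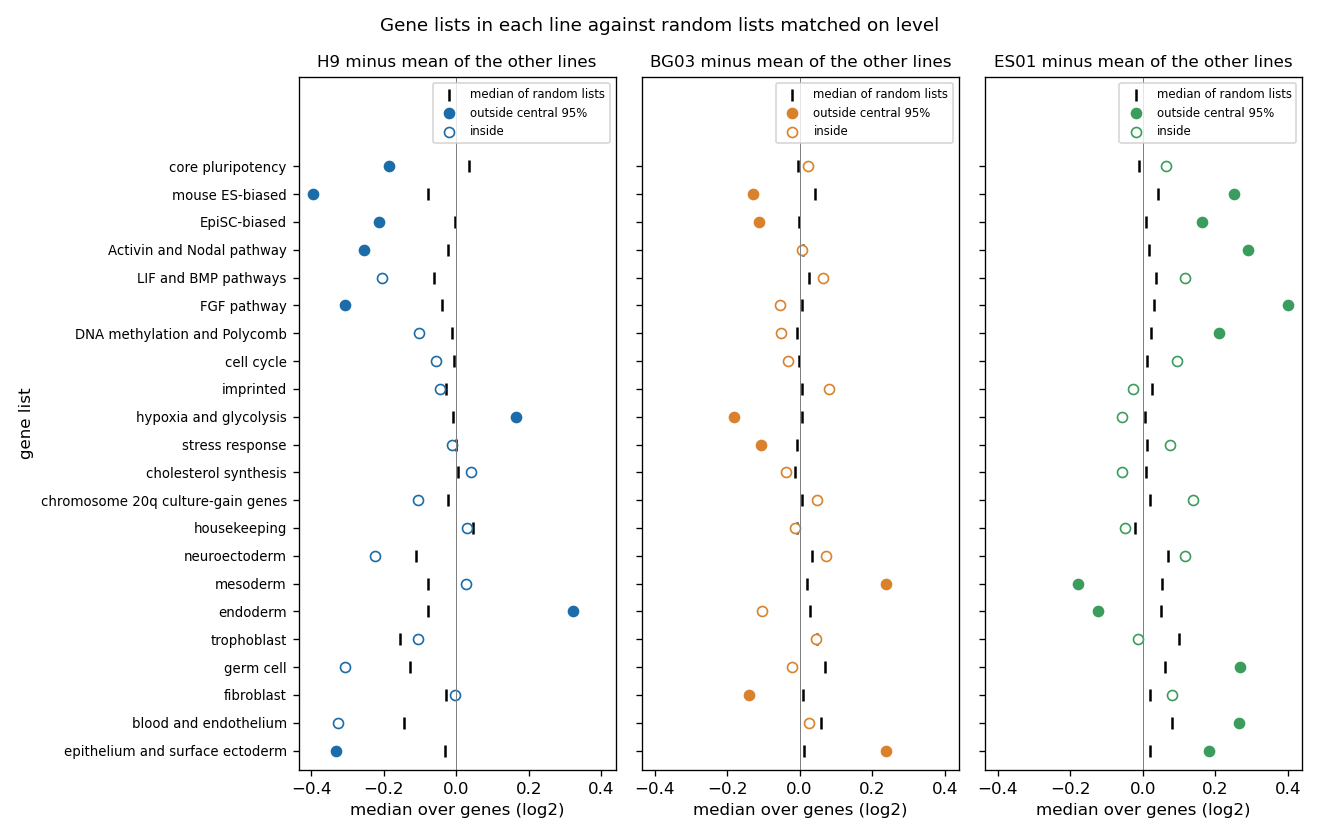
Median over genes of each line minus the mean of the other lines (x axis, log2) for the 22 gene lists (y axis), with 1 panel per line; filled circles lie outside the central 95% of random lists, open circles inside, and bars mark the median of random lists. In H9 the mouse ES-biased list sits lowest at -0.40 and the endoderm list highest at 0.32, and in ES01 the FGF list sits highest at 0.40.

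Genes were also grouped by autosome. Of 66 pairs of autosome and line 13 had an adjusted random-list permutation p under 0.05, and all 13 were small shifts. Relative to random lists, the genes of autosomes 2, 4, 5 and 13 were lower in BG03 and those of 16, 17, 20 and 22 higher. The BG03 calls held under 9 of 9 alternatives for autosomes 13 and 16, under 8 for 2, 4 and 5, under 7 for 22, under 6 for 17 and under only 3 for 20 (adjusted permutation p = 0.0477). In ES01, again relative to random lists, the genes of autosomes 4 and 5 were higher and those of 17, 19 and 22 lower. The ES01 calls held under 7 of 9 alternatives for autosome 4 and 8 for the others. The farthest from random lists was autosome 13 in BG03, at a distance of -0.09 (adjusted permutation p = 0.0026). Its median was -0.07, with 161 of 269 genes lower than the mean of the other lines. A gain to 3 copies in place of 2 would give 0.58. With a line left out there are 22 pairs in place of 66, of which 13 were called without H9, 0 without BG03 and 2 without ES01.

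**Figure D3:**
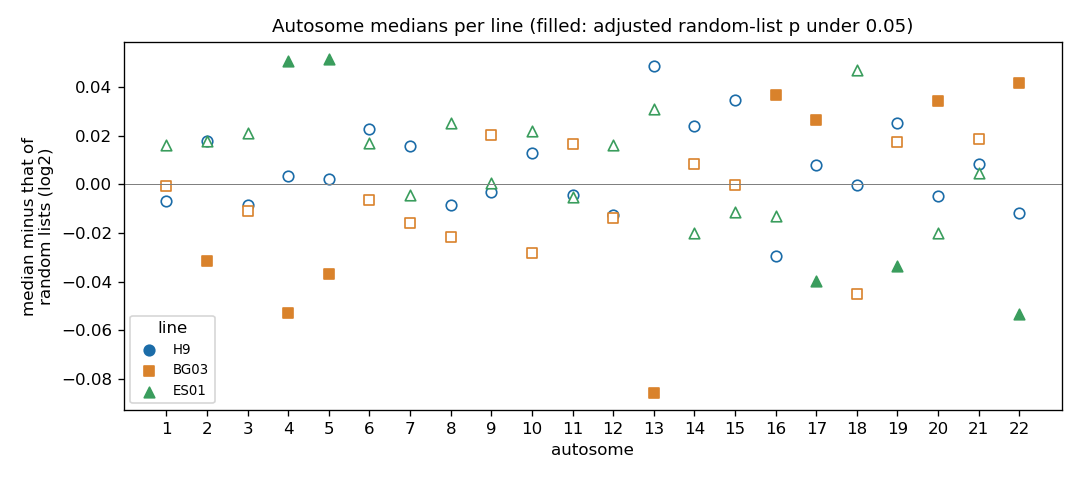
Distance of each autosome's median from that of random lists (y axis, log2) for the 22 autosomes (x axis) in each line, filled where the adjusted random-list permutation p is under 0.05. The points lie within 0.09 of 0 for every autosome and line, and those of BG03 and ES01 lie on opposite sides at autosomes 4, 5, 17 and 22.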

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

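The test of whole-autosome gain or loss, the comparison for dim probes on the H9 array and the split of the probe test into parts were chosen after their results had been seen. A signal lay in probes that no comparison used: of 14196 measured probes that matched no reference gene, 9799 (69.0%) were well above background on all 3 arrays, against 85.6% of the matched probes. A difference of at least 2-fold in a line from each of the other lines was counted 669 times among them (4.71 per 100 probes) and 991 times among 26680 matched probes (3.71 per 100); a probe can count for 2 lines and a gene can have several probes, so these counts were not tested. Their median signal was 64.8 intensity units against 265 for matched probes.

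The 695 differences of single lines might come from a sequence variant or defect under a single probe, in which case about 50% of a gene's other probes would differ in the same direction. For all genes but those higher in H9, 91.10% of 146 other probes did (interval 85.3 to 95.2%), which argues against probe defects as the whole cause there. Within these the count was 26 of 33 for genes lower in ES01. Only other probes well above background on the brighter side were counted, which favours the called direction, so the share under defects may exceed 50%. Several probes can belong to 1 gene, so the interval may be too narrow. For genes higher in H9 the share was 63.64% of 44 (interval 47.8 to 77.6%), too few probes to exclude them, and for genes with no other probe well above background, such as BEX5, ARMCX5 and IAH1, nothing in the tables bears on it. Line, culture and slide position stay open, since each line has 1 array.

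The autosome shifts in BG03 and ES01 could reflect a gain or loss of a whole autosome in most cells, but the largest distance from random lists was 0.086, against 0.58 for 1 extra copy; a small share of cells or part of an autosome was not tested. They followed gene density instead. Over the 22 autosomes Spearman's rho between genes per megabase and distance from random lists was 0.778 in BG03 (permutation p = 8e-05, adjusted 0.00012; Pearson's r 0.53, permutation p = 0.0013, adjusted 0.00195) and -0.839 in ES01 (permutation p = 2e-05, the smallest 100000 permutations can give, adjusted 6e-05; r -0.63, permutation p = 0.00068, adjusted 0.00195). In H9 rho was -0.203 (permutation p = 0.366) and r -0.01 (permutation p = 0.984). Without autosomes 17 and 19, the farthest in density, r was 0.80 in BG03, -0.68 in ES01 and -0.58 in H9. The shifts of the lines share their arrays, so BG03 and ES01 are not independent, and a trend along RNA or probe properties that go with gene density may account for these shifts; no biological explanation was tested.

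The endoderm list was higher in H9. A trend of dim probes on that array would move matched random lists as well, and their median was -0.0782 while the endoderm list was at 0.32. The list had been called by this same comparison, so it is no separate test of such a trend. Endoderm-like cells in the H9 culture may be a candidate source. An added list of liver and yolk sac secreted proteins, with its test fixed beforehand, lay at the 10.16 percentile of random lists in H9 (median -0.25); 18 of its 28 genes had at least 10 times the signal of the negative controls in every line. The list as a whole was thus not higher in H9. Of its 26 genes well above background in at least 1 line, 9 were higher and 17 lower. The median was -0.32 against BG03 alone (bootstrap interval over genes -0.57 to 0.03) and -0.19 against ES01 alone (-0.38 to 0.14). These values argue against endoderm-like cells that express the list as a whole. Single members went both ways. RBP4 (-2.49 against -3.75 and -3.69), FGA and FGG had their highest level in H9. TF (-3.97 against -3.40 and -2.95) and AMBP (-4.31 against -3.27 and -3.17) had their lowest level there. APOE was at 4.98 in H9 against 4.97 and 5.22 and APOC1 at 2.18 against 1.94 and 2.03. With members that go both ways, endoderm-like cells that express part of the list and a change of single genes within the ES cells cannot be told apart.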

How the results depend on the processing

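Of the list shifts outside the random range, 5 changed sign under an alternative: DNA methylation and Polycomb in ES01 gave -0.0011 with all probes of a gene averaged, and with a line left out mouse ES-biased in BG03 ran from -0.3484 to 0.2252, EpiSC-biased in BG03 from -0.1259 to 0.0489, endoderm in ES01 from -0.5 to 0.1771, and epithelium and surface ectoderm in BG03 from -0.008 to 0.3991. The line left out sets which single line remains to compare with. For each value below the cause was not tested unless the setting itself gives it. The added threshold of 100 times the negative controls gave 8358 detected genes, a gap of -51.7 percentage points between mouse ES-biased and EpiSC-biased genes and 13 lists detected apart from all genes; 10 times gave 6 lists. The 2 lists detected apart became 0 with the 99th percentile of negative controls, 0 with limma and 0 with a flag on at least 1 array, settings under which nearly all genes are detected. For genes apart, in the order higher in H9, lower in H9, higher in BG03, lower in BG03, higher in ES01 and lower in ES01 (127, 127, 64, 128, 179 and 70), normexp gave 45, 59, 25, 28, 56 and 31 (244 in all), the 1.5-fold threshold 483, 497, 253, 369, 560 and 369 (2531 in all) and the 4-fold threshold 22, 36, 7, 27, 35 and 6 (133 in all), the last 2 by construction. Only genes well above background on all 3 arrays gave 84 higher in H9, 42 higher and 77 lower in BG03 and 119 higher in ES01. No filter on dim probes gave 195 lower in H9 and 97 higher in BG03. With a line left out only 1 other line remains to differ from, which raises the counts to 347 to 392, 275 to 510, 193 to 275, 347 to 426, 426 to 510 and 193 to 392. The 25 pairs of list and line became 5 to 9 with a line left out, of 22 in place of 66 by construction; the 11 lists with a wide spread became 7 with all probes averaged and 5 to 8 with a line left out; the 13 autosome shifts of 66 pairs became 0 to 13 of 22. Of the differences of named genes 329 values under alternatives stayed past 2-fold and 7 did not; of the list shifts 533 kept their side of the random range, 34 left it, 5 changed sign and 22 entered it; of mean levels 508 moved by less than 1 SD and 124 by more, 79 of them under median centring, which shifts every level. Signal over background limits genes near the background, where 1225 genes were detected in no line.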

Other observations

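The protocadherin tests below were chosen after their results had been seen. The hypoxia and glycolysis list had missed the adjusted threshold in H9 (median 0.16, adjusted permutation p = 0.078). It had passed that threshold as lower in BG03 (median -0.18, adjusted permutation p = 0.0088). A second set of HIF targets, none of them in that list, was higher in H9. Of the 28 genes 21 were higher there, with a median of 0.28, and the median was -0.15 in BG03 and in ES01. FAM162A, a mitochondrial protein induced by hypoxia, was at 4.09 in H9 against 3.21 and 3.25, BNIP3L at 1.68 against 0.79 and 1.03, P4HA2, a collagen prolyl hydroxylase, at 0.62 against -0.12 and -0.07, and EGLN1, an oxygen-sensing prolyl hydroxylase, at -0.98 against -1.71 and -2.37. AK4 and BHLHE40 went the other way, at 4.27 against 4.56 and 5.27 and at -4.36 against -3.62 and -2.89.

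The hypothesis of a HIF-target response in the H9 culture predicted, before that list was looked at, a place above the central 95% of random lists. The list lay at the 100 percentile in H9 (random-list permutation p = 0.0002, the smallest 10000 lists can give) and on the same side under 9 of 9 alternatives. This is consistent with such a response, but a culture grown to higher density, the line itself and the slide position may equally account for it, since H9 has 1 array.

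The protocadherin beta genes were lower in BG03 as a family, with a median of -1.03 and 16 of 17 genes lower. Without the 3 members named by the rule 13 of 14 were lower (median -0.86). A change along the whole protocadherin cluster in BG03 could explain this, and the alpha and gamma genes did lie at the 0.14 percentile of random lists in BG03. Set against H9 alone, however, the median of the 19 alpha and gamma genes was -0.089 (95% bootstrap interval over genes -0.29 to 0.15), while that of the beta genes was -0.91 (-2.32 to -0.44), which argues against a drop of the whole cluster by at least 0.5 relative to H9. Set against ES01 the alpha and gamma genes of BG03 were lower too, at -0.49 (-0.89 to -0.20) with 16 of 19 lower. The beta genes were at -1.04 (-1.71 to -0.77). The alpha and gamma genes of ES01 were also above those of H9, by 0.61 (0.16 to 0.73) with 16 of 19 higher. Their gap to ES01 was thus not particular to BG03 and does not show a drop of the whole cluster there. Some members nearly matched each other in every line. PCDHA1 was at -0.63, -0.92 and 0.71 in H9, BG03 and ES01, and PCDHA5 at -0.52, -0.87 and 0.71. Among the beta genes PCDHB11 was at 0.68, -0.48 and 1.23, and PCDHB2 at 0.67, -0.33 and 1.17. Whether their probes read the same RNA was not tested. The genes may thus not be independent, and the counts and intervals may overstate the precision.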
